A study of Mus musculus with 6 samples.

How the data were processed

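RNA of differentiated mouse brown adipocytes was measured on 6 one-colour oligonucleotide arrays, with biotin-labelled total RNA, per the labels. The groups came from the sample titles: wild type, PGC-1α knockout with a control siRNA, and PGC-1α knockout with an siRNA against PGC-1β, with 2 arrays each. The series design calls the replicates biological. The cells had been immortalised with the SV40 large T antigen, per the labels, and were taken on day 7 of differentiation.

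The authors deposited 1 intensity per probe set and array, on a linear scale, for 45037 probe sets. The software that summarised the probes, the scaling between arrays and any background correction are not given in the sources used here. The array medians lay between 220.9 and 242.7, so the table was taken as already scaled and was not scaled again in the main analysis. The highest intensity on an array lay between 14016 and 15531, and how far probe sets near that level still respond to more RNA was not tested. Detection calls and control probe sets (names starting with AFFX) were not among the values used here, so the ratio of 3' to 5' control signals could not be formed.

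Cells of the table without a number were of 2 kinds. There were 5285 cells that held the word null, in probe sets whose median intensity on the other arrays was 39.46. A further 870 cells were empty, in probe sets with a median of 315.3 on the other arrays, against 227.8 over all probe sets. The empty cells numbered 17 and 26 on the wild-type arrays, 334 and 106 on the knockout-control arrays and 27 and 360 on the knockdown arrays. Both kinds were kept as missing.

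Probe sets were named through the platform annotation of 2016, with symbols updated by Entrez identifier in a gene table of assembly GRCm38. One symbol was given for 34945 probe sets, several for 932 and none here for 9160. Of those with 1 symbol, 34741 matched the gene table. The 10092 probe sets with several symbols or none were not used. Each of 18193 genes was represented by its probe set with the highest mean log2 value over the 6 arrays. Genes whose mean lay under the 40th percentile of all probe sets (7.61 on the log2 scale, an intensity of 163.6) were left out, which left 13658 genes, 314 of them with a missing cell.

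Values were transformed as log2(intensity + 32), so fold changes are on that scale and understate the change of dim genes. One limma model (version 3.58.1, R 4.3.3) was fitted to all 6 arrays with group means only, and eBayes moderated the spread with 3 residual and 5.46 prior degrees of freedom. A gene was called when its p, adjusted by Benjamini-Hochberg over the genes tested in that comparison, was under 0.05. Adjusted p-values in the text are from this limma model unless another test is named. The 3 comparisons were knockout-control minus wild type, knockdown minus knockout-control, and knockdown minus wild type. With 2 arrays per group the number of arrays limits the precision, and an exact permutation test of 2 against 2 arrays cannot reach p = 0.05, so none was used.

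Before the data were examined, 22 gene lists, the model, the alternatives and the rule for named genes were fixed. The lists covered mitochondrial pathways, thermogenic and adipocyte genes, lipid and glucose metabolism, antioxidant and stress responses, matrix, interferon response, cell cycle, sex-linked genes and markers of other cell types. List members passing over all genes were counted, and also after adjustment over the list alone. List shifts were tested two-sidedly with camera of limma at a preset inter-gene correlation of 0.01, on members with a value on every array, for lists of at least 3 such genes. The 63 tests, 21 lists in 3 comparisons, were adjusted together by Benjamini-Hochberg. With a correlation estimated from the data none of the 63 passed, against 26 with the preset value. All 63 adjusted p-values with an estimated correlation lay between 0.848 and 0.996. That form rests on 3 residual degrees of freedom. It has little power here, and a call lost under it does not tell lists apart. The estimated correlations reached 0.744 (cell cycle), above the preset of 0.01, so p-values at the preset can be too small. The self-contained test fry, which asks whether list genes move one way on balance, also passed none (lowest adjusted p = 0.0583). Its mixed form, which takes changes in either direction, passed 46.

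Named genes were a fixed set of coactivators, thermogenic, adipocyte and respiratory genes, the 8 called genes with the highest and the 8 with the lowest fold change in each comparison whose groups did not overlap, and up to 4 called members of each list with the largest change. Not overlapping happens for 33.3% of genes by chance with 2 against 2 arrays. For the coactivators each probe set was given. Genes with only a clone or accession identifier were counted and not described. Of the fixed genes, Cpt1b had no probe set named for it alone and was not tested.

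The procedure was tested on simulated data with the moderated spread of each gene on the real arrays. The simulated errors were drawn independently for each gene and array, without correlation between genes or a deviation shared by arrays. False calls in such data therefore do not show how often real calls, or camera at its preset correlation, are wrong. In the simulated comparison of knockdown with knockout-control, over 13649 genes, 17.9% of genes changed by 0.5 log2 were called, 89.6% of those changed by 1 and 100% of those changed by 2. The shares were 13.4%, 98.5% and 100% for knockout-control against wild type (13652 genes) and 10.4%, 94% and 100% for knockdown against wild type (13644 genes). Of the calls made in these simulated comparisons, 14 of 158, 13 of 161 and 16 of 160 were of unchanged genes, in the same order, and 1 unshifted list was called in the last. In 20 simulated sets without any change, at most 3 genes were called in a comparison.

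The alternatives were quantile normalization, median centring, pseudocounts of 8 and 128, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, eBayes with trend and robust settings, only the arrays of the 2 groups compared, the replicate number as a block, each array left out in turn, an adjusted p under 0.01 and a minimum change of 2-fold. Added after the data were seen were null cells set to 0, crossed replicate numbers as a block, and leaving out both arrays with over 300 empty cells. The test of the difference between the 2 steps (knockout, then knockdown) was also chosen after the data were seen. Plots were drawn with matplotlib 3.10.9.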

Results

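Brown preadipocytes of 3 kinds were turned into adipocytes and profiled on day 7 to compare cells with both PGC-1 coactivators, cells without PGC-1α, and cells without PGC-1α in which PGC-1β was also knocked down. PGC-1α (Ppargc1a) and PGC-1β (Ppargc1b) are transcriptional coactivators that raise the expression of mitochondrial genes. The groups were wild type, PGC-1α knockout carrying a control siRNA (knockout-control) and PGC-1α knockout carrying an siRNA against PGC-1β (knockdown), with n = 2 arrays each. The replicates are called biological in the series design. The titles of the wild-type cells name no siRNA, and a passage number, 4, was given for wild type only, so genotype, siRNA vector and cell line cannot be separated in any comparison with wild type. Over the genes above the filter with a value on every array, the log2 values of 2 arrays of one group correlated with r = 0.989 in wild type. The correlation was 0.978 in knockout-control and 0.963 in the knockdown group. These correlations are across genes, which are not independent replicates, and dim genes were left out. Knockdown array 1 correlated slightly more with knockout-control array 2 (r = 0.967) than with the other knockdown array.

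The targeted genes were examined first. Ppargc1b had 1 probe set, with a mean intensity of 3006 ± 221 (SD, n = 2) in wild type, 2082 ± 311 in knockout-control and 378.8 ± 219 in the knockdown group. It fell 5.53-fold between knockout-control and knockdown cells (log2 fold change -2.47 ± 0.32 SE, limma adjusted p = 0.022), and its change between wild type and knockout-control did not pass (-0.53 ± 0.32, limma adjusted p = 0.397). Without either knockout-control array the fall of Ppargc1b no longer passed (highest limma adjusted p = 0.145), while its log2 fold change stayed between -3.04 and -1.89 with each array left out in turn. All 5 probe sets of Ppargc1a were dimmer in knockout-control than in wild type, at 0.553 to 0.617 of the wild-type intensity, and 3 of them passed (limma adjusted p = 0.0436, 0.037 and 0.0484, against 0.0656 and 0.125 for the others). The deleted part of Ppargc1a and the probe positions are not given in the sources used here, so the remaining signal of 296 to 798.9 in knockout-control checks little about the deletion. Pprc1, the third family member, had log2 fold changes of 0.35 ± 0.16 and 0.11 ± 0.16 in the 2 steps and was not called (limma adjusted p = 0.25 and 0.809).

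**Figure D1:**
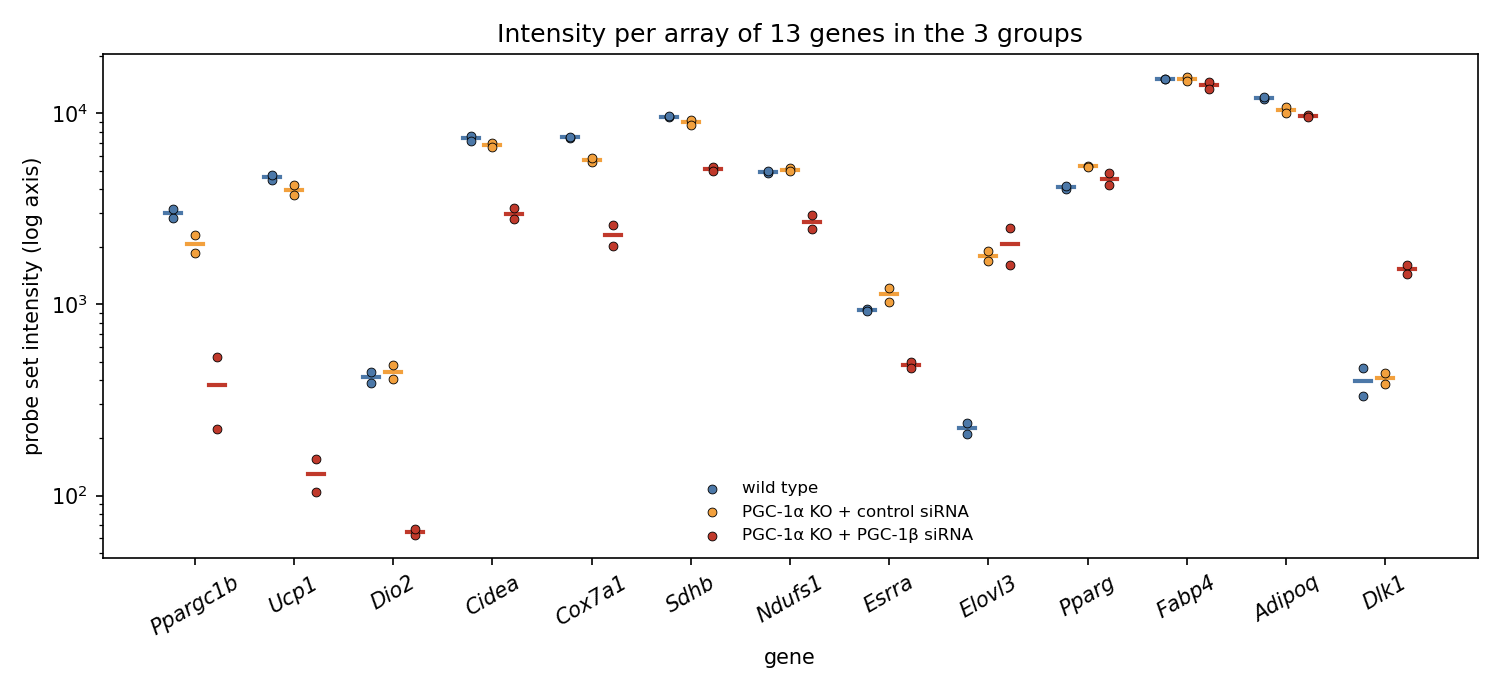
Probe set intensity (log axis) of 13 genes in wild-type, knockout-control and knockdown cells; points are single arrays, n = 2 per group, and horizontal bars are group means. Mean Ucp1 intensity was 4625 in wild type, 3962 in knockout-control and 130.2 in knockdown cells, while Elovl3 stood at 224.5, 1795 and 2069.

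Knockout-control cells were compared with wild-type cells, which differ in PGC-1α, cell line and sex-linked transcripts and, as far as the labels tell, in siRNA vector. Ucp1, the uncoupling protein that makes heat in brown fat, had mean intensities of 4625 ± 193 (SD, n = 2) in wild type and 3962 ± 335 in knockout-control, a difference that did not pass (log2 fold change -0.22 ± 0.18 SE, limma adjusted p = 0.546). Elovl3, an elongase of very long chain fatty acids found in brown fat, rose 7.12-fold (2.83 ± 0.21, limma adjusted p = 0.000349). On the scale of log2(intensity + 32), whose pseudocount sets the order among genes dim in 1 group, the largest rises were those of Sult1a1, a sulfotransferase (15.1-fold, 3.91 ± 0.16), Agt, which encodes angiotensinogen (11.6-fold, 3.53 ± 0.16), the homeobox gene Hoxd8 (10.6-fold, 3.41 ± 0.21) and Ifi207 (10.5-fold, 3.39 ± 0.25). Rarres1, the cytochrome P450 gene Cyp2b10 and Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 9.32-fold, 7.59-fold and 6.85-fold. The largest falls were those of the homeobox gene Hoxc8 (14-fold, -3.81 ± 0.20) and of the immunoproteasome subunits Psmb8 (12.9-fold, -3.69 ± 0.23) and Psmb9 (8.34-fold, -3.06 ± 0.19). Car9, a carbonic anhydrase, fell 7.68-fold, Ptp4a3 7.44-fold, the transferrin receptor gene Tfr2 7.15-fold, the cell cycle inhibitor Cdkn1c 6.73-fold and Hmgn3 6.15-fold. The 2 groups did not overlap for 58.2% of all genes tested, against 33.3% by chance, and limma adjusted p-values of these 16 genes lay between 6.2e-05 and 0.000551. This scale understates the change of dim genes such as Ifi207, at 18.38 in wild type, below the intensity of the filter.

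Of 13652 genes tested, 348 were higher and 478 lower in knockout-control (limma with Benjamini-Hochberg), with 2885 at an unadjusted p under 0.05 against 683 expected by chance. The change was at least 2-fold for 156 of the higher and 196 of the lower genes. A second probe set above the filter had the opposite sign for 46 of the 398 called genes that had several, with 5 of 39 and 86 of 629 in the other comparisons (knockdown against knockout-control and against wild type). The count moved with single arrays: 238 and 234 genes passed without wild-type array 1 or 2, 232 and 340 without knockout-control array 1 or 2, and 1786 without either knockdown array, and 178 genes passed in each of the 6 fits. Of the 72 genes named here that were called in this comparison, 36 kept the call in all 6 fits and 32 in 4 or fewer. The count was 364 with no filter on dim genes, 474 with the mean of a gene's probe sets and 1653 after quantile normalization.

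Of 71 measured members of the oxidative phosphorylation list, 0 rose, 1 fell and 70 did not pass, and 0 passed when adjusted over the list alone. The member that fell was Atp5g1, an ATP synthase subunit (1.58-fold, -0.66 ± 0.14, limma adjusted p = 0.0312). Atp5g1 did not pass without any 1 of the wild-type and knockout-control arrays (highest limma adjusted p = 0.263). The list's median log2 fold change was -0.06 (camera adjusted p = 0.226), and without knockout-control array 1 the list passed at a median of -0.09 (camera adjusted p = 0.03). Sdhb, Cycs, Cox4i1 and Atp5b, genes of complex II, cytochrome c, complex IV and ATP synthase, had log2 fold changes from -0.09 to 0.08. Of 18 tricarboxylic acid cycle genes, 1 rose, Pcx, which encodes pyruvate carboxylase (1.98-fold), and 0 fell. Of 25 fatty acid oxidation genes, 0 rose and 3 fell, namely Acaa1b (1.87-fold), Acaa1a (1.73-fold) and the carnitine carrier Slc25a20 (1.73-fold). Acaa1a and Acaa1b are close copies, and probes shared between them were not ruled out. The tricarboxylic acid cycle and fatty acid oxidation lists did not shift (camera adjusted p = 0.78 and 0.666). Of 73 mitochondrial ribosome genes, 0 rose and 4 fell (2 when adjusted over the list alone), with Mrps6 down 2-fold and Mrpl3 1.63-fold, at a list median of -0.13 (camera adjusted p = 0.0327). That call was lost without wild-type array 1 or knockout-control array 1 (median -0.04 without the latter, camera adjusted p = 0.202, and -0.22 without knockout-control array 2), after quantile normalization (0.176) and with an estimated correlation (adjusted p = 0.848 with an estimated correlation). None of 29 genes of mitochondrial import and genome maintenance passed in limma, and the list median was -0.16 (camera adjusted p = 0.0947; 0.0341 in the mixed form of fry).

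Thermogenic and adipocyte genes moved in both directions. Of 24 measured brown fat thermogenic genes, 4 rose and 6 fell (4 and 7 when adjusted over the list alone), and the list did not shift as a whole (median -0.08, camera adjusted p = 0.404). Its median lay between -0.13 and -0.06 with each array left out in turn. Beside Elovl3, Pank1, a kinase of coenzyme A synthesis, rose 3.63-fold and Mpzl2 2.12-fold, and Kcnk3 also rose, while Eva1b fell 2.28-fold. Eva1b is a separate gene from Mpzl2, whose other name is Eva1, and its place in the list was not checked. The other members that fell were Zic1, Plin5, Slc25a20, Ebf2 and Letmd1. The values of Cidea (-0.11 ± 0.14), Dio2 (0.09 ± 0.15), Cox7a1 (-0.40 ± 0.16), Cox8b (-0.80 ± 0.24), Prdm16 (-0.22 ± 0.14) and Ppara (0.04 ± 0.14) did not pass. Of 27 genes of general adipocyte differentiation, 6 rose and 2 fell (8 and 2 when adjusted over the list alone), and the list shifted up (median 0.10, camera adjusted p = 0.0188). Over members with a value on every array the median was 0.14, and 0.08 without wild-type array 2. The list call was lost without knockout-control array 1 (camera adjusted p = 0.0717) and with an estimated correlation (adjusted p = 0.848 with an estimated correlation). The transcription factor gene Cebpd rose 5.68-fold, the resistin gene Retn 2.81-fold and the phosphatidate phosphatase Lpin1 2.23-fold, and Sncg fell 3.2-fold. Pparg, Fabp4 and Adipoq, general adipocyte genes, had values of 0.37 ± 0.14, -0.00 ± 0.14 and -0.21 ± 0.14 and did not pass. Fabp4, at 15190 in wild type, held the highest intensity on each array of these 2 groups and on knockdown array 1. How far it could still change at that level was not tested, which limits its values in each comparison.

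Of 26 extracellular matrix genes, 0 rose and 9 fell (2 and 16 when adjusted over the list alone), among them Fn1, fibronectin (3.98-fold), Thbs1 (2.71-fold), Col6a3 (2.56-fold) and Timp3 (2.48-fold), at a median of -0.55 (camera adjusted p = 1.8e-07). Of 20 antioxidant genes, 0 rose and 7 fell (1 and 11 when adjusted over the list alone), led by the extracellular superoxide dismutase Sod3 (6-fold), Gclc (2.77-fold), Gpx7 (2.47-fold) and Gpx1 (2.16-fold), at a median of -0.50 (camera adjusted p = 1.65e-05). Of 18 glycolysis genes, 1 rose and 5 fell (1 and 8 when adjusted over the list alone). The hexokinase Hk1 fell 2.96-fold while Hk2, the other hexokinase of the list, rose 2.02-fold, and Aldoc fell 2.86-fold and the lactate carrier Slc16a3 2.74-fold, at a list median of -0.27 (camera adjusted p = 0.00222; median -0.18 without knockout-control array 1). Of 24 interferon response genes, 0 rose and 4 fell (6 when adjusted over the list alone). The 4 were Psmb8, Psmb9, Tap1, a peptide transporter of antigen presentation (2.49-fold), and Ifit2 (2.29-fold), at a list median of -0.09 (camera adjusted p = 0.0249, lost without wild-type array 1 at a median of -0.03 and 0.221). Its median was -0.22 without wild-type array 2, -0.04 without knockout-control array 1 and -0.14 without knockout-control array 2. After quantile normalization the interferon call was lost at an adjusted p of 0.0562, and with a filter at the 60th percentile the median was 0.04. Each of these 4 list calls was lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation).

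For the remaining lists the lowest camera adjusted p between knockout-control and wild type was 0.0947. Of 19 genes of fatty acid and triglyceride synthesis, 5 rose and 1 fell (7 and 1 when adjusted over the list alone), with Mlxipl, a carbohydrate-responsive transcription factor, up 2.87-fold, Acacb 2.39-fold and Acly 1.94-fold, and this list, at a camera adjusted p of 0.0952, passed without knockout-control array 2 (0.0341), with a filter at the 60th percentile (0.0423) and with trend and robust settings (0.038). Fasn stood at 0.51 ± 0.14 and did not pass (limma adjusted p = 0.0754). Of 20 cholesterol synthesis genes, 3 rose and 1 fell (4 and 4 when adjusted over the list alone), with Cyp51 up 2.13-fold and Sqle down 1.71-fold. Foxo1 (1.87-fold) and Rxra (1.79-fold) rose among 27 transcriptional partners of PGC-1, while Esrra (0.26 ± 0.15), Nrf1 (0.41 ± 0.14) and Gabpa (-0.62 ± 0.18) did not pass. Klf2 (5.64-fold) and Gata3 (1.68-fold) rose among 16 preadipocyte and fibroblast markers. Herpud1 (1.49-fold) rose among 19 genes of the unfolded protein and integrated stress response, and Kif23 fell 1.65-fold among 28 cell cycle genes, a list with a median of 0.00 and a camera direction of down. Of 8 smooth muscle and pericyte markers, Tagln fell 2.62-fold, Cspg4 1.61-fold and Acta2 1.54-fold, but with the mean of its probe sets Acta2 stood at 0.44 (limma adjusted p = 0.179). None of 9 skeletal muscle, 8 macrophage and 4 endothelial markers passed in limma, where 0 of each were also called over the list alone.

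The wild-type and knockout cells differed in sex-linked transcripts. Eif2s3y, on the Y chromosome, had intensities of 872 and 961 on the 2 wild-type arrays and 6.25 and 5.13 on the knockout-control and knockdown arrays with a value. Kdm5d and Uty, also Y-linked, stood at 205 and 218 and at 278 and 295 in wild type, and at no more than 62 and 49.9 in the other 4 arrays. Xist, expressed from an inactive X chromosome, stood at 57.9 and 116 in wild type and at 3409, 4307 and 2593 on the 3 other arrays with a value for that probe set. These are values of the probe set with the widest difference for each gene, and some other probe sets of Uty, Xist and Kdm5d did not separate wild type from the other cells. One of Uty stood at 479 and 433 in wild type against 341 to 464 on the other arrays, and one of Xist at 196 and 199 against 182 to 253. A probe set of Kdm5d stood at 172 and 171 in wild type against 90.2 to 204. A further probe set of Xist held the word null on both wild-type arrays and stood at 849 to 1648 on the other 4. By the probe sets that separated them, the wild-type cells read as male and the knockout cells as female. Sex therefore cannot be separated from genotype in any comparison with wild type.

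Knockdown cells were compared with knockout-control cells, which share the genotype, to examine the added lowering of PGC-1β. The titles name a control siRNA and an siRNA against PGC-1β, without a further siRNA or a rescue. Effects of the siRNA on other genes, and differences between the cell populations carrying each siRNA, therefore cannot be separated from the loss of PGC-1β. This limit holds for every gene and list in the knockdown step. Ucp1 fell 24.9-fold, from 3962 ± 335 to 130.2 ± 36.1 (SD, n = 2; log2 fold change -4.64 ± 0.18 SE, limma adjusted p = 3.44e-05), to an intensity below that of the filter on dim genes. Dio2, the deiodinase that activates thyroid hormone, fell 4.93-fold from 444.5 ± 50.2 to 64.38 ± 3.31 (-2.30 ± 0.15, limma adjusted p = 0.00051). Mb, myoglobin, fell 6.33-fold (-2.66 ± 0.16, limma adjusted p = 0.000458). Cox7a1, a muscle and brown fat form of a cytochrome c oxidase subunit, and Cidea, a lipid droplet protein of brown fat, fell 2.46-fold and 2.28-fold (limma adjusted p = 0.0193 and 0.0167). Without either knockout-control array neither Cox7a1 nor Cidea passed (highest limma adjusted p = 0.134 and 0.138). Elovl3 stayed at 0.17 ± 0.21 and Pparg, Fabp4 and Adipoq at -0.22 ± 0.14, -0.11 ± 0.14 and -0.11 ± 0.14, with none of these 4 passing.

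Among the other genes with the largest falls were the adhesion receptor Adgrg6 (9.65-fold, limma adjusted p = 0.000458), the chloride channel Ano1 (4.99-fold, limma adjusted p = 0.000458) and the tubulin gene Tubb2a (4.55-fold, limma adjusted p = 0.0406). The chemokine Cxcl12 was among the genes that rose most (3.58-fold, 1.84 ± 0.15, limma adjusted p = 0.00182), with Dlk1, a marker of preadipocytes (3.53-fold), Gas6 (3.48-fold) and Scara5 (2.87-fold). Ly6e, the lipopolysaccharide-binding protein gene Lbp, Chac1 and Tmem45b rose 2.78-fold, 2.76-fold, 2.7-fold and 2.7-fold. Of 13649 genes tested, 37 were higher and 77 lower in knockdown cells (limma with Benjamini-Hochberg), 26 and 50 of them by at least 2-fold, with 1930 at an unadjusted p under 0.05 against 682 expected by chance.

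These calls depended on single arrays: 13 and 8 genes passed without knockout-control array 1 or 2, 538 and 145 without knockdown array 1 or 2, and 47 without either wild-type array. The 8 genes that passed in each of the 6 fits were Ucp1, Dio2, Mb, Adgrg6, Ano1, Adamts1 and a gene known by an accession, which fell, and Cxcl12, which rose (Adamts1 was named after its values were seen). Of the 35 genes named here that were called in this step, 7 kept the call in all 6 fits and 27 in 4 or fewer, and no called gene changed sign. Lower genes made up 67.5% of the calls, against 49.6% after quantile normalization and 52.1% after median centring. The count was 9 with no filter, 13 with the mean of a gene's probe sets, 71 with a smaller and 254 with a larger pseudocount, 199 with a filter at the 60th percentile, 325 with trend and robust settings and 381 after quantile normalization. With the replicate number as a block it was 22, and 769 with crossed replicate numbers, a choice made after the data were seen.

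Of 71 oxidative phosphorylation genes, 69 had a log2 fold change below 0, 0 rose, 3 fell over all genes tested, and 58 fell when adjusted over the list alone. The list median was -0.60, a level of 0.661 of that in knockout-control (camera adjusted p = 3.37e-34), and adjusted p = 0.848 with an estimated correlation. The median lay between -0.67 and -0.52 with each array left out in turn. The 3 genes called over all genes were Ndufs1 of complex I (1.87-fold), Uqcr11 of complex III (1.82-fold) and Sdhb of complex II (1.75-fold, 9006 ± 360 against 5120 ± 197), and each passed in 1 of the 6 fits without an array, that without knockdown array 1 (highest limma adjusted p of Sdhb = 0.263). All 33 complex I, 4 complex II, 9 complex III and 8 complex IV genes had values below 0, with medians of -0.61, -0.78, -0.64 and -0.46, and 14 of 15 ATP synthase genes did so at a median of -0.58. Complexes were assigned by the start of the gene symbol here and below, so Ndufa4 was counted with complex I without a check of its complex. The very bright genes Cox4i1 (-0.30 ± 0.14), Atp5b (-0.19 ± 0.14) and Cycs (-0.66 ± 0.17) did not pass.

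Of 18 tricarboxylic acid cycle genes, 0 rose and 4 fell (13 when adjusted over the list alone), namely Ogdh (2.43-fold), Idh3b (1.93-fold), Dlst (1.84-fold) and Sucla2 (1.74-fold), at a list median of -0.51 (camera adjusted p = 4.02e-12). Of 25 fatty acid oxidation genes, 1 fell, the acyl-CoA dehydrogenase Acadvl (1.89-fold), and 1 rose, Pdk4 (2.28-fold), a kinase that inhibits pyruvate dehydrogenase, at a list median of -0.22 (camera adjusted p = 0.0164). The latter list did not pass without knockout-control array 1 or knockdown array 1 (highest camera adjusted p = 0.127). Of 73 mitochondrial ribosome genes, 0 rose and 1 fell, Mrpl34 (1.79-fold; 4 when adjusted over the list alone), at a list median of -0.15 (camera adjusted p = 4.26e-05). Without knockdown array 2 the mitochondrial ribosome median was -0.01 (camera adjusted p = 0.0928), without knockdown array 1 it was -0.34 and without knockout-control array 2 it was -0.07. None of 29 genes of mitochondrial import and genome maintenance passed in limma and 5 fell when adjusted over the list alone, at a median of -0.21 (camera adjusted p = 0.000335; median -0.33 without knockdown array 1 and -0.10 without knockdown array 2). These 4 list calls were lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation).

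Of 24 brown fat thermogenic genes, 6 fell and 1 rose (9 and 1 when adjusted over the list alone), at a list median of -0.28 (camera adjusted p = 4.26e-05, and adjusted p = 0.848 with an estimated correlation). The median was -0.45 without knockdown array 1 and -0.20 without knockdown array 2. Ucp1, Dio2, Cox7a1, Cidea, the mitochondrial deacetylase Sirt3 and Letmd1 fell, and Pdk4 rose. None of 27 genes of general adipocyte differentiation passed in limma over all genes or over the list alone, at a list median of -0.14 (camera adjusted p = 0.0947; 0.00314 in the mixed form of fry), and without knockout-control array 2 the list passed at a median of -0.18 (camera adjusted p = 0.035). Esrra, an orphan nuclear receptor that binds PGC-1 coactivators, fell 2.26-fold (-1.18 ± 0.15, limma adjusted p = 0.0202; up to 0.134 without either knockout-control array) among 27 transcriptional partners, as did Sirt3 (2.05-fold), while Nrf1 (-0.13 ± 0.14), Gabpa (-0.57 ± 0.18), Tfam (-0.54 ± 0.15), Ppara (-0.04 ± 0.14) and Prdm16 (-0.39 ± 0.14) did not pass. Acacb fell 1.86-fold among 19 genes of fatty acid and triglyceride synthesis, and Fasn, at -0.30 ± 0.14, did not pass. Of 18 glycolysis genes Aldoc rose 2.42-fold and Ldhb fell 2.61-fold. Dlk1 rose among 16 preadipocyte and fibroblast markers, a list whose median was -0.07 and whose camera direction was up (camera adjusted p = 0.941). The lists of partners, of fatty acid and triglyceride synthesis and of glycolysis did not shift (camera adjusted p = 0.209, 0.164 and 0.482).

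Lists that shifted up in knockdown cells had few called members. Of 26 extracellular matrix genes, 2 rose, the gelatinase Mmp2 (2.23-fold) and Col6a2 (1.86-fold), and 0 fell (6 and 1 when adjusted over the list alone), at a list median of 0.21 (camera adjusted p = 1.65e-05). None of 24 interferon response genes passed in limma over all genes, and 7 rose when adjusted over the list alone, at a list median of 0.35 (camera adjusted p = 2.28e-06; 0.128 in the mixed form of fry). Of 19 genes of the unfolded protein and integrated stress response, 1 rose, Chac1, a glutathione-degrading enzyme, at a list median of 0.13 (camera adjusted p = 0.00507). For the members of this list with a value on every array the median was 0.09, against 0.03 and 0.18 without knockout-control array 1 or 2 and 0.24 without knockdown array 2, and the highest camera adjusted p was 0.05 without knockdown array 1. None of 28 cell cycle genes passed in limma, at a list median of 0.11 (camera adjusted p = 0.0259). The cell cycle call was lost without knockdown array 1 (median 0.01, camera adjusted p = 0.429), without knockout-control array 2 (median 0.22, 0.0725), with the mean of a gene's probe sets (0.674) and with no filter (0.0778), and the median was 0.33 without knockdown array 2. These 4 list calls were lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation). Between the 2 knockdown arrays the median gene differed by -0.20 (array 2 minus array 1), and the mean log2 values of the interferon, stress, cell cycle and mitochondrial ribosome lists by -0.31, -0.30, -0.34 and -0.35. None of the skeletal muscle, smooth muscle and pericyte, macrophage and endothelial markers, of the antioxidant genes or of the cholesterol synthesis genes passed in limma, and the lowest camera adjusted p of these 6 lists was 0.108. That was the cholesterol list, which passed without knockdown array 2 (camera adjusted p = 0.0332).

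**Figure D2:**
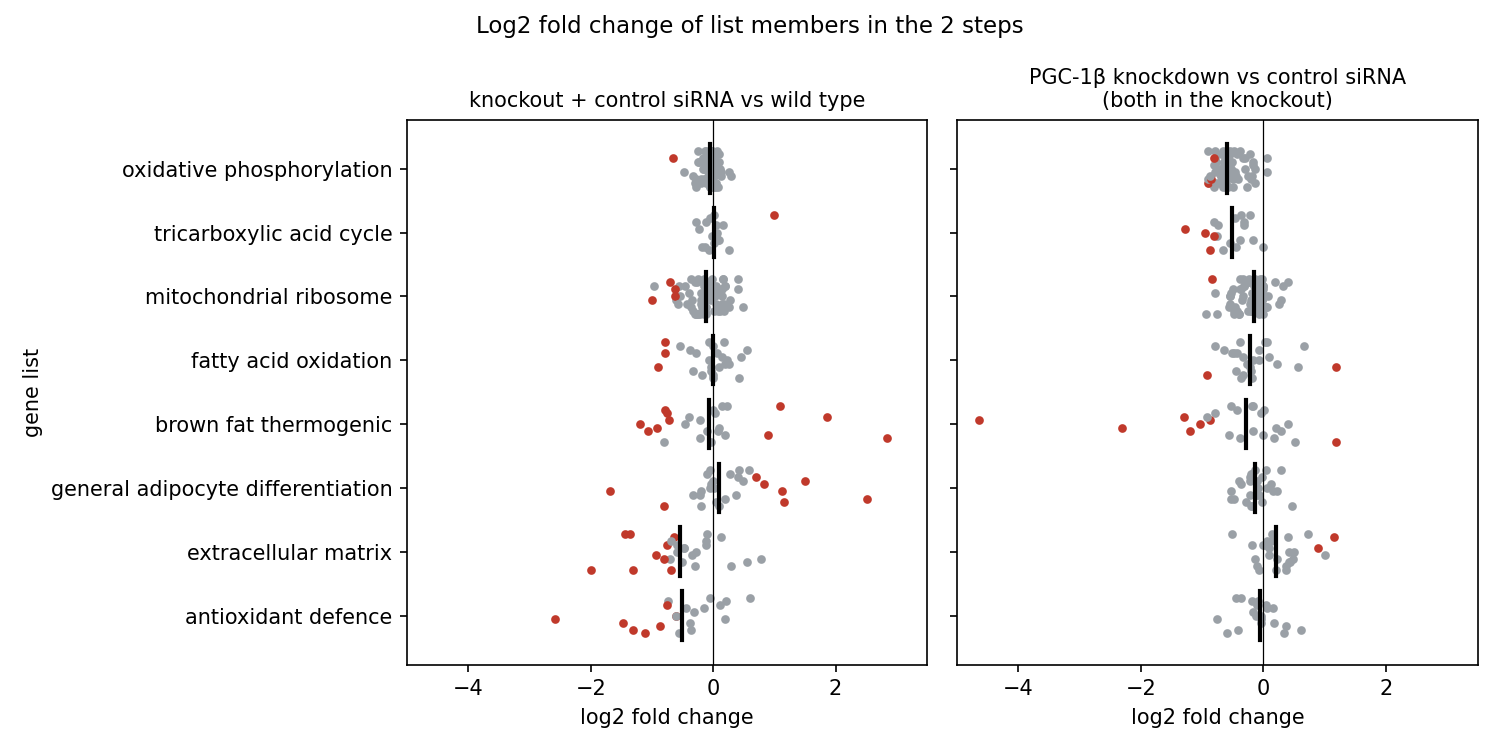
Log2 fold change (horizontal axis) of each measured member of 8 gene lists, for knockout-control minus wild type (left) and knockdown minus knockout-control (right); red points passed limma with an adjusted p under 0.05, grey points did not, and black bars are list medians. The oxidative phosphorylation median stood at -0.06 on the left and -0.60 on the right, and the extracellular matrix median at -0.55 and 0.21.

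Knockout cells with PGC-1β knocked down were compared with wild type, as the sum of the 2 steps. Ucp1 fell 29.1-fold (-4.86 ± 0.18, limma adjusted p = 2.06e-05), Mb 12.9-fold, Ppargc1b 7.97-fold, Dio2 4.64-fold, Cox7a1 3.24-fold and Cidea 2.46-fold. Elovl3 rose 8.01-fold. Rarres1, Agt, Sult1a1, Ifi207 and Hoxd8 rose 16.2-fold, 15.7-fold, 15.1-fold, 13.4-fold and 11.1-fold, and Mndal, a relative of Ifi207 in a multigene family whose probes can overlap, and Tmem182 rose 7.35-fold and 7.22-fold. Hoxc8, Car9, Adgrg6 and Cdkn1c fell 14.4-fold, 12.9-fold, 8.67-fold and 7.85-fold. Of 13644 genes tested, 546 were higher and 819 lower (limma with Benjamini-Hochberg), 179 and 268 of them by at least 2-fold.

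Of 71 oxidative phosphorylation genes, 0 rose, 44 fell and 27 did not pass (60 fell when adjusted over the list alone), at a list median of -0.62 (camera adjusted p = 6.52e-24). The genes that fell included 23 of 33 of complex I, 3 of 4 of complex II, 6 of 9 of complex III, 3 of 8 of complex IV and 9 of 15 of ATP synthase. Ndufs5 fell 2.26-fold, Ndufb10 2.26-fold, Ndufa5 2.24-fold and Ndufb7 2.03-fold. Of 18 tricarboxylic acid cycle genes, 10 fell and Pcx rose (13 and 1 when adjusted over the list alone), with Ogdh down 2.87-fold (list median -0.56, camera adjusted p = 2.6e-06). Of 73 mitochondrial ribosome genes, 15 fell (21 when adjusted over the list alone), with Mrpl47 down 2.31-fold and Mrps25 2.43-fold (list median -0.30, camera adjusted p = 8.83e-07; median -0.48 without knockdown array 1 and -0.12 without knockdown array 2). Of 29 genes of import and genome maintenance, 8 fell (11 when adjusted over the list alone), among them Timm10 (2.21-fold), Tomm40 (1.91-fold) and Tfam, which packages mitochondrial DNA (1.58-fold; list median -0.34, camera adjusted p = 6.53e-05). Of 25 fatty acid oxidation genes, 7 fell and 2 rose (10 and 3 when adjusted over the list alone), with Slc25a20 down 2.31-fold and Pdk4 up 2.22-fold (list median -0.24, camera adjusted p = 0.0405, lost without wild-type array 2, either knockout-control array or knockdown array 1, at up to 0.0938, and after quantile normalization at 0.095). These 5 list calls were lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation).

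Of 24 brown fat thermogenic genes, 11 fell and 3 rose (12 and 4 when adjusted over the list alone), at a list median of -0.45 (camera adjusted p = 0.00402, and adjusted p = 0.848 with an estimated correlation). Prdm16, a determinant of brown fat identity, fell 1.52-fold but passed in 1 of the 6 fits without an array, that without knockdown array 1 (highest limma adjusted p = 0.276). Slc25a20, Sirt3 (2.82-fold) and Eva1b (1.71-fold) were among the others that fell. Of 27 general adipocyte genes, 6 rose and 2 fell (7 and 2 when adjusted over the list alone), with a list median of 0.02 (camera adjusted p = 0.227). Cebpd rose 3.93-fold, Klf15 2.54-fold and Retn 2.13-fold, and Sncg fell 2.86-fold. Pparg (0.15 ± 0.14), Fabp4 (-0.11 ± 0.14), Adipoq (-0.32 ± 0.14), Ppara (-0.00 ± 0.14), Nrf1 (0.28 ± 0.14), Fasn (0.21 ± 0.14), Cycs (-0.59 ± 0.17), Cox4i1 (-0.29 ± 0.14), Atp5b (-0.27 ± 0.14) and Cox8b (-0.29 ± 0.24) did not pass. Gabpa, a regulator of respiratory genes, fell 2.29-fold and Esrra 1.89-fold, and Rxra rose 2.24-fold, among 27 partners whose median of 0.13 and mean of -0.02 differ in sign (camera adjusted p = 0.666).

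Among the other lists, 9 of 20 antioxidant genes fell (14 when adjusted over the list alone), with Sod3 down 6.16-fold and the mitochondrial superoxide dismutase Sod2 2.22-fold (list median -0.60, camera adjusted p = 2.24e-06). Of 18 glycolysis genes, 4 fell and 1 rose (6 and 2 when adjusted over the list alone), with Ldhb down 4.44-fold, Slc16a3 3.26-fold and Hk1 3.21-fold and Pfkfb3 up 2.03-fold (list median -0.33, camera adjusted p = 0.00402; median -0.20 without knockdown array 2). Of 19 stress response genes, 3 rose (6 when adjusted over the list alone), Chac1 (2.48-fold), Atf3 (1.85-fold) and Herpud1 (1.58-fold; list median 0.33, camera adjusted p = 0.0145; median 0.16 without knockdown array 1). Of 8 smooth muscle and pericyte markers, 3 fell, Tagln (4.12-fold), Acta2 (1.78-fold) and Cspg4 (1.65-fold; list median -0.17, camera adjusted p = 0.0474, lost without any 1 of the knockout-control and knockdown arrays, at up to 0.11, with medians of -0.33 without knockdown array 1 and -0.10 without wild-type array 2, and after quantile normalization at 0.095), and with the mean of its probe sets Acta2 stood at 0.00 (limma adjusted p = 0.994). These 4 list calls were also lost with an estimated correlation (adjusted p = 0.848 with an estimated correlation). Of 26 extracellular matrix genes 7 fell and 2 rose (10 and 4 when adjusted over the list alone; camera adjusted p = 0.0952, and 0.0288 without wild-type array 2), with Fn1 down 4.16-fold, Thbs1 3.84-fold and Mmp2 up 2.44-fold. Of 16 preadipocyte and fibroblast markers 4 rose and 0 fell, Dlk1 (3.66-fold), Klf2 (3.48-fold), Pdgfra (1.87-fold) and Twist2 (1.56-fold; camera adjusted p = 0.122). Of 20 cholesterol synthesis genes 3 rose and 2 fell, with Cyp51 up 2.43-fold and Dhcr7 down 2.05-fold. Mlxipl rose 2.25-fold and Elovl6 fell 1.52-fold among 19 genes of fatty acid and triglyceride synthesis, and this list and the cholesterol list did not shift (camera adjusted p = 0.236 for each). Psmb8 (6.42-fold), Psmb9 (5.95-fold) and Tap1 (1.92-fold) fell and Ifih1 rose 1.68-fold among 24 interferon response genes, whose median of 0.20 and mean of -0.08 differ in sign (camera adjusted p = 0.482). No cell cycle, skeletal muscle, macrophage or endothelial marker passed in limma, and these lists had camera adjusted p-values from 0.164 to 0.666. Without knockdown array 2 the cell cycle list passed (camera adjusted p = 0.00973).

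The count of genes that differed between knockdown cells and wild type was 355 and 326 without wild-type array 1 or 2, 992 without either knockout-control array, 2339 without knockdown array 1 and 1572 without knockdown array 2, and 275 genes passed in each of these fits. Of the 110 genes named here that were called in this comparison, 56 kept the call in all 6 fits and 47 in 4 or fewer. Lower genes made up 60% of the calls, against 44.9% after quantile normalization, 50.1% after median centring, 77.2% without knockdown array 1 and 40.1% without knockdown array 2.

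The difference between the 2 steps was tested directly, as the knockdown step minus the knockout step. The oxidative phosphorylation list lay lower in the knockdown step, by a median of -0.54 (camera adjusted p = 5.79e-12), as did the tricarboxylic acid cycle list (-0.69, camera adjusted p = 2.49e-06) and the thermogenic list (-0.22, camera adjusted p = 0.0227). The general adipocyte list also lay lower (-0.31, camera adjusted p = 0.00915), after its rise in the knockout step (median 0.10). The extracellular matrix list (0.94, camera adjusted p = 6.28e-11), the interferon list (0.54, camera adjusted p = 2.19e-05) and the antioxidant list (0.52, camera adjusted p = 0.00915) lay higher in the knockdown step. The antioxidant list did not rise in the knockdown step itself (median -0.06, camera adjusted p = 0.481). Its difference reflects its fall in the knockout step (median -0.50). None of these list differences held with an estimated correlation (adjusted p = 0.758 with an estimated correlation). By gene, 226 passed in limma, among them Ucp1 (-4.41 ± 0.31, limma adjusted p = 0.00287), Dio2 (-2.39 ± 0.26, limma adjusted p = 0.00565), Elovl3 (-2.66 ± 0.37, limma adjusted p = 0.0132) and Esrra (-1.43 ± 0.26, limma adjusted p = 0.0373), but not Cidea (-1.08 ± 0.25, limma adjusted p = 0.0787), Cox7a1 (-0.90 ± 0.28, limma adjusted p = 0.169) or Sdhb (-0.72 ± 0.24, limma adjusted p = 0.193). The difference of Elovl3 reflects its rise in the knockout step (2.83), as it stood at 0.17 in the knockdown step.

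Of the genes called in both steps, 6 were lower in both (Mb, Ldhb, Letmd1, Ccn2, Fbln5 and Gstk1), against 2.7 for independent lists, and 1 was higher in both (Scara5), against 0.9. A further 8 rose in the first step and fell in the second (2 for independent lists), and 10 fell and then rose (1.3 for independent lists), among them Aldoc, Gas6 and Ly6e. The 2 steps share the knockout-control arrays with opposite signs, so an array's chance deviation enters both in opposite directions, and with 2 such arrays they could not be split. Ccn2, Fbln5 and Gstk1 were named after their values were seen.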

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

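Null cells at 0, the crossed replicate numbers and leaving out both arrays with over 300 empty cells were chosen after the data were seen. The count of called genes is given as higher and lower, and list values are median log2 fold changes of members with a value on every array. With an array left out its group has 1 array, which is assumed to vary like the other groups. Unless stated, the cause of a change was not tested.

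Between knockout-control and wild type, 348 genes were higher and 478 lower. Quantile normalization gave 725 and 928, median centring 427 and 722, no filter 168 and 196, the mean of a gene's probe sets 215 and 259, the arrays of these 2 groups alone 719 and 1067, and the replicate number as a block 192 and 217. An adjusted p under 0.01 left 127 and 139 and a change of at least 2-fold 156 and 196, fewer by construction. Leaving out both arrays with over 300 empty cells gave 1081 and 954. With 1 array left out the higher count ranged from 111 (without knockout-control array 2) to 719 (without either knockdown array), and the lower count from 102 (without knockout-control array 1) to 1067 (without either knockdown array).

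Between knockdown and knockout-control, 37 genes were higher and 77 lower. Quantile normalization gave 192 and 189, median centring 80 and 87, the smaller pseudocount 27 and 44, the larger pseudocount 76 and 178, no filter 2 and 7, the 60th percentile filter 56 and 143, the mean of a gene's probe sets 1 and 12, and trend and robust settings 85 and 240. The arrays of these 2 groups alone gave 17 and 30 and the replicate block 8 and 14. An adjusted p under 0.01 left 4 and 9 and a change of at least 2-fold 26 and 50. With 1 array left out the higher count ranged from 1 (without knockout-control array 2) to 75 (without either knockdown array), and the lower count from 7 (without knockout-control array 2) to 463 (without knockdown array 1).

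Between knockdown and wild type, 546 genes were higher and 819 lower. Quantile normalization gave 1269 and 1032, median centring 848 and 851, no filter 242 and 345, the mean of a gene's probe sets 319 and 459, the replicate block 293 and 433, an adjusted p under 0.01 gave 169 and 231 and a change of at least 2-fold 179 and 268. Leaving out both arrays with over 300 empty cells gave 1976 and 1366. With 1 array left out the higher count ranged from 151 (without wild-type array 1) to 941 (without knockdown array 2), and the lower count from 174 (without wild-type array 2) to 1806 (without knockdown array 1).

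Equal replicate numbers are not stated to pair the arrays, and crossing them between the knockout-control and knockdown groups gave 832 and 1209, 306 and 463, and 1161 and 1662 genes in the 3 comparisons, in the order given above. With null cells at 0 the counts were 349 and 477, 37 and 76, and 550 and 824. No setting moved the median of all genes by over 0.1.

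The oxidative phosphorylation list (-0.60 in the knockdown step, -0.635 against wild type) and the thermogenic list (-0.284 and -0.445) stayed below 0 in those comparisons under each alternative. The thermogenic median in the knockdown step ranged from -0.15 with the larger pseudocount to -0.45 without knockdown array 1, with -0.17 with no filter and -0.43 with the mean of a gene's probe sets. Against wild type it ranged from -0.15 with no filter to -0.77 with the mean of a gene's probe sets, with -0.26 with the larger pseudocount and -0.71 with the 60th percentile filter. Both lists passed in camera in these comparisons except with an estimated correlation (adjusted p = 0.848 for each) and were also not called by fry (adjusted p = 0.0583 for each). Between knockout-control and wild type the oxidative phosphorylation list, at -0.06, passed without knockout-control array 1 (adjusted p = 0.03) and at -0.085 without both arrays with over 300 empty cells (adjusted p = 0.008), within a range of 0.008 to 0.957. Its values with 1 array left out ranged from -0.087 to -0.048. The general adipocyte list rose between these groups by 0.14 and did not pass without knockout-control array 1 (adjusted p = 0.0717), with an estimated correlation (0.848), with fry (0.214) or, at 0.051, without both arrays with over 300 empty cells (0.176), within a range of 0.00387 to 0.848. Its values with 1 array left out ranged from 0.085 to 0.197. In the knockdown step this list, at -0.16, passed with trend and robust settings (adjusted p = 0.00955) and without knockout-control array 2 (adjusted p = 0.035), within a range of 0.00955 to 0.848. There its values with 1 array left out ranged from -0.218 to -0.084.

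Of the values of named genes under the alternatives, 6790 kept their side of the threshold, 232 came to pass, 615 no longer passed and 2 reversed. Both reversals were of Acta2 with the mean of its probe sets, at 0.44 (adjusted p = 0.179) between knockout-control and wild type and 0.003 (adjusted p = 0.994) between knockdown and wild type. Of the values of all lists, 1215 kept their side of the threshold, 12 came to pass and 93 no longer passed. These were from camera, except for the alternative of fry, which gave 37 of the 1215 and 26 of the 93. A median near 0 could change sign within these counts, as that of the general adipocyte list between knockdown and wild type did (0.03, and -0.074 without knockdown array 1). The number of arrays limits the counts, and genes near the background, with a mean under an intensity of 163.6 at the filter, were left out except with no filter.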

Other observations

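The Hox gene test was narrowed after its first outcome was seen, and the growth state test relative to the median gene was chosen after the result was seen. The oxygen and glucocorticoid lists were written after the top genes were seen, without the genes that prompted them, and were tested again without named genes and members of the other lists, a choice also made after the result was seen.

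Of 15 measured members of a list of glucocorticoid-responsive genes, 9 rose in knockout-control against wild-type cells (60% against 2.49% of other genes, two-sided Fisher's exact p = 1.79e-11), with a median log2 fold change of 1.16. Zbtb16 rose most (2.32 ± 0.14 SE, limma adjusted p = 0.000141), with Tsc22d3 (1.58 ± 0.15), Sgk1 (1.61 ± 0.27) and Lpin1 (1.16 ± 0.15) among the others. Klf9, counted among the 9, had a value on 1 knockout-control array only (1.31 ± 0.20). Dusp1 (-0.54 ± 0.23), Rora (-0.52 ± 0.21), Mt1 (-0.07 ± 0.14) and Mt2 (-0.07 ± 0.14), also members, did not pass. Rasd1, a glucocorticoid target left out of the list because its value had been seen, fell (-2.44 ± 0.23, limma adjusted p = 0.000829). In the knockdown step the list median was -0.04 and 1 member, Per1, rose (limma adjusted p = 0.0387). Without Lpin1, also a member of the general adipocyte list and already examined there, 8 of 14 rose (57.1%, two-sided Fisher's exact p = 4.32e-10), at a median of 0.90. Fisher's test, here and for the other gene groups below, counts genes as independent draws. All genes were measured on the same arrays, so a difference between cultures or lines can move many of them together. The Fisher p-values therefore do not measure the spread between cultures and can be too small.

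Of 26 measured members of a list of oxygen-responsive genes, 4 fell, 1 rose and 21 did not pass in knockout-control against wild-type cells (15.4% lower, against 3.48% of other genes, two-sided Fisher's exact p = 0.012), with a median of -0.20. The 4 were Ndrg1 (-1.78 ± 0.40), Egln3 (-1.06 ± 0.20), Lox (-0.94 ± 0.14) and Egln1 (-0.61 ± 0.15), while Hk2 rose. Their limma adjusted p-values were 0.0379, 0.02, 0.00731 and 0.0469, in that order, so the calls of Ndrg1 and Egln1 lay near the threshold. Ndrg1 stood at 1267 ± 864 (SD, n = 2) in knockout-control. Hk2, Slc2a1, Pdk1, Ldha, Pgk1 and Pfkfb3 are also in the glycolysis list and Lox in the extracellular matrix list, and were already examined there. Without these 7 genes 3 of 19 fell (15.8%, two-sided Fisher's exact p = 0.0272), at a median of -0.28. Adm (0.58 ± 0.24), Mxi1 (0.50 ± 0.16), Angptl4 (0.48 ± 0.14), Vegfa (0.13 ± 0.26) and Bnip3 (-0.00 ± 0.14) did not pass.

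The strongest changes between knockout-control and wild-type cells included Fkbp5 and Car9. A stronger glucocorticoid response and a weaker oxygen response of the knockout cells are candidate explanations, at medians of 0.90 and -0.28 over the members not examined before, each carried by part of its list only, and both were tested on the data that prompted them. Dexamethasone or oxygen exposure, cell line, sex, siRNA vector and the lack of PGC-1α itself stay open. Genotype, line, sex and vector cannot be separated between these groups. The list values were not recomputed with arrays left out.

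The genes that differed between the knockout and wild-type cells could reflect the lines as well as PGC-1α. Passenger DNA on the chromosome of Ppargc1a as the whole cause is argued against, since this chromosome's share of the called genes was 0.861 times its share of the tested genes (0.633 to 1.14; 45 of 822 called genes). Of the 100 tested genes nearest to Ppargc1a, 4 were called, against 6.07% of other genes. The sex chromosomes held 1.38 times their share (0.973 to 1.9, 36 of 822 called genes, Fisher's exact p = 0.0501). Of the 4 genes of the sex-linked list on the arrays, 1 was tested here, Uty, at a log2 fold change of -0.047. That value is from its brightest probe set, which did not separate the lines (479 and 433 against 417 and 464 in knockout-control). A dimmer probe set of Uty stood at 278 and 295 in wild type and at 49.1 and 17.8 in knockout-control. The share thus leaves out transcripts that separated the lines, so it does not settle how far sex-linked genes contributed. Most called genes lay on other chromosomes, where effects of sex stay open. A different positional origin of the lines cannot be told apart from the genotype, with 2 of 19 Hox genes other than Hoxc8 and Hoxd8 called (10.5% against 6.04%, two-sided Fisher's exact p = 0.321) and 4 of 21 with them (p = 0.0349).

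Knockout-control array 1 and knockdown array 2 deviated from their partners in a shared direction: across genes, which are not independent replicates, the differences between replicates 1 and 2 of the 2 groups correlated with r = -0.502. The correlation was -0.467 after quantile normalization, which argues against scaling of the arrays as the whole cause. The cell cycle list mean differed by -0.34 between knockdown arrays 2 and 1 and by -0.09 between knockout-control arrays 1 and 2 (interval -0.145 to -0.043), but the median gene differed by -0.20 and -0.12 between the same arrays. Relative to the median gene the list differed by 0.026 between knockout-control arrays 1 and 2 (interval -0.025 to 0.077) and by -0.14 between knockdown arrays 2 and 1. These lie on opposite sides, but both intervals compare 2 single arrays and can reflect only the spread over list genes. Those genes are correlated (estimated at 0.744), so the intervals are too narrow and a shared slower growth state was not decided. These are also the 2 arrays with the most empty cells, 334 and 360 against 17 to 106 on the others. The correlation of -0.502 was taken over genes with a value on every array, so the empty cells do not enter it, but whether their origin also moved other values was not tested. No labels give a batch or a day of processing, and the cause stays open.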
